A study of Homo sapiens with 13 samples.

How the data were processed

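Messenger RNA of IMR-90 fibroblasts seeded on tissue culture polystyrene was measured on 13 Affymetrix oligonucleotide arrays for human genes, of which 12 had a time after seeding (1h, 2h, 4h, 8h, 12h, 24h or 48h) that the title and the description shared. The values used are the signal intensity per probe set that the authors deposited, 1 value per probe set and array on a linear scale. The table holds 22283 probe sets, with 0 missing values and 0 values at or below 0. How the authors summarised probes, corrected background and scaled arrays is not given in the sources used here, and neither are detection calls. The median deposited signal per array ran from 134 to 153.2, so whether the arrays had been scaled to each other by the authors stays unknown. The number of arrays limits the precision.

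After 68 control probe sets were left out, 22215 remained. The 12 arrays were quantile normalised, signals below the 20th percentile (46.74) were raised to it, and log2 was taken. Probe sets whose mean over the 12 arrays was above the 50th percentile of probe set means were tested, which left 11107. Of the values tested, 0.0285% were at the floor. Gene symbols came from the platform annotation supplied with the table. Of the 22215 probe sets, 19065 named 1 gene, 1043 several and 2107 none, and no gene was named from a probe set with several. Of those with 1 symbol, 19053 were found in a RefSeq gene table, which changed 0 symbols, and 11963 different genes were named. A gene was represented by its probe set with the highest mean signal, giving 6938 genes with a tested probe set, and no second probe set of a named gene passed the threshold in the other direction.

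Tests used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The slope of log2 signal on log2 hours used all 12 arrays (10 residual degrees of freedom). The contrasts of 4h, 8h and 12h with 2h and the F test among these 4 times used 1 fit on their 9 arrays (5 residual degrees of freedom). The single arrays of 1h, 24h and 48h were compared with the mean of 2h without a test, with list medians set against 10000 random lists of the same size matched on mean signal. The 27 gene lists were tested with limma's camera where 5 or more members were tested (25 lists), with the preset correlation of 0.01 and with an estimated correlation, adjusted over the 25 lists. They covered immediate early genes, inflammatory cytokines and NF-kB targets, G1/S and DNA replication, G2/M and mitosis, collagens and extracellular matrix, matrix proteases, integrins and focal adhesion, actin cytoskeleton, TGF-beta targets, hypoxia and glycolysis, angiogenic factors, cholesterol synthesis, the unfolded protein response, heat shock proteins, oxidative stress and metallothioneins, p53 targets, quiescence and FOXO genes, ribosome biogenesis, cytoplasmic ribosomal proteins, the mitochondrial respiratory chain, the proteasome, interferon-induced genes, fibroblast identity, and epithelial, endothelial, leukocyte and smooth muscle markers.

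The designs, the lists, the gene rule and the alternatives not said to be later were fixed before the data were examined. The rule named, for the slope, up to 12 called genes in each direction whose slope had 1 sign within codes 1 and 2; for each contrast, up to 10 called genes in each direction without overlap between the groups, or those with the smallest p where fewer than 5 were called; the 10 genes with the smallest F test p not called along the slope; up to 4 members of each list by slope p and 2 by F test p; 17 fixed genes, of which 15 had a tested probe set and the others are not analysed here; and the 6 largest differences in each direction at 24h and 48h outside the range of all arrays up to 4h. The text prints those that matter. Genes named from the fit with the block beyond this rule were chosen after their values were seen.

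Arrays were grouped by the time in their labels. The number in the titles, called the title code, was checked as a pairing of the arrays of 2h, 4h and 12h, where codes 1 and 2 each hold 1 array. Over 11107 probe sets the deviations of same-code arrays from their group means correlated at 0.723 between 2h and 4h, 0.482 between 2h and 12h and 0.554 between 4h and 12h. The codes were therefore taken to pair these samples, and fits with the code as a replicate block are given beside results that they change. The blocked slope had 6 residual degrees of freedom and the blocked contrasts, on 6 arrays, 2. Both 8h arrays share a code of their own, so 8h entered no contrast with the code as a fixed block, and only the random block included it.

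The steps were tested on simulated data built on the 11107 probe sets with 100 changed at each size. Without a code shift, the slope fit without the block recovered 97 of 100 slopes of size 0.3 and 100 of 100 of size 0.6, and the contrast of 12h with 2h recovered 67 of 100 log2 changes of 1 and 95 of 100 of size 2. With a simulated code shift, these became 65, 97, 3 and 73 without the block and 76, 98, 23 and 90 with it.

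Alternatives were median scaling, the values as deposited, other floors, other dim-probe filters, eBayes without a trend, 1 probe set per gene, the mean over all probe sets of a gene for lists, the code as a fixed or a random block, codes 2 and 4 merged, slopes within 1 code, over 2h to 12h or on ranks, a fit on all 12 arrays, and leaving out each array in turn. Added after seeing the data were leaving out 4h replicate 3 and the 48h array together, the GAPDH ratio as a covariate, leaving out each array for the blocked slope and for the lists, other scalings and no filter for the blocked fits, and a blocked fit on all arrays of codes 1 and 2. The array with disagreeing times was left out of normalisation, filtering and all tests, and was scaled to the same distribution to give its values.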

Results

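IMR-90 is a line of human fetal lung fibroblasts that attaches to plastic and divides for a limited number of passages. Its messenger RNA was measured on Affymetrix arrays at 7 times after the cells were seeded on tissue culture polystyrene, the treated plastic of ordinary culture dishes. Of 13 arrays, 12 had a time on which the title and the description of the sample matched. There was 1 array at 1h, 2 at 2h, 3 at 4h, 2 at 8h, 2 at 12h, 1 at 24h and 1 at 48h. The remaining array was titled 12 h and described as 30 min, so it entered no comparison. The labels do not say that arrays of one time came from separate cultures, so every p-value measured only the spread between these samples, which may be technical. The number of arrays limited the precision. The question was which genes change with time on this surface, and no other surface was analysed here.

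The arrays fell into 5 sets by a number in their titles, called the title code here. Code 1 held the arrays of 1h, 2h replicate 1, 4h replicate 1 and 12h replicate 1, and code 2 held 2h replicate 2, 4h replicate 2, 12h replicate 2 and the array of 24h. Code 4 held both 8h arrays, and 4h replicate 3 and the 48h array each had a code of their own. In code 2 the titles of 2h and 24h also carry the letter B and those of 4h and 12h the letter A, which no fit took into account. The deposited median signal per array lay between 134 and 153.2. The first and second principal components took 30.3% and 29.1% of the variance. The array 4h replicate 3 had the lowest mean Spearman correlation with the other arrays, 0.942, and the highest ratio of GAPDH 3' to 5' signal, 1.66. The lowest ratio among the 12 arrays was 0.962.

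**Figure D1:**
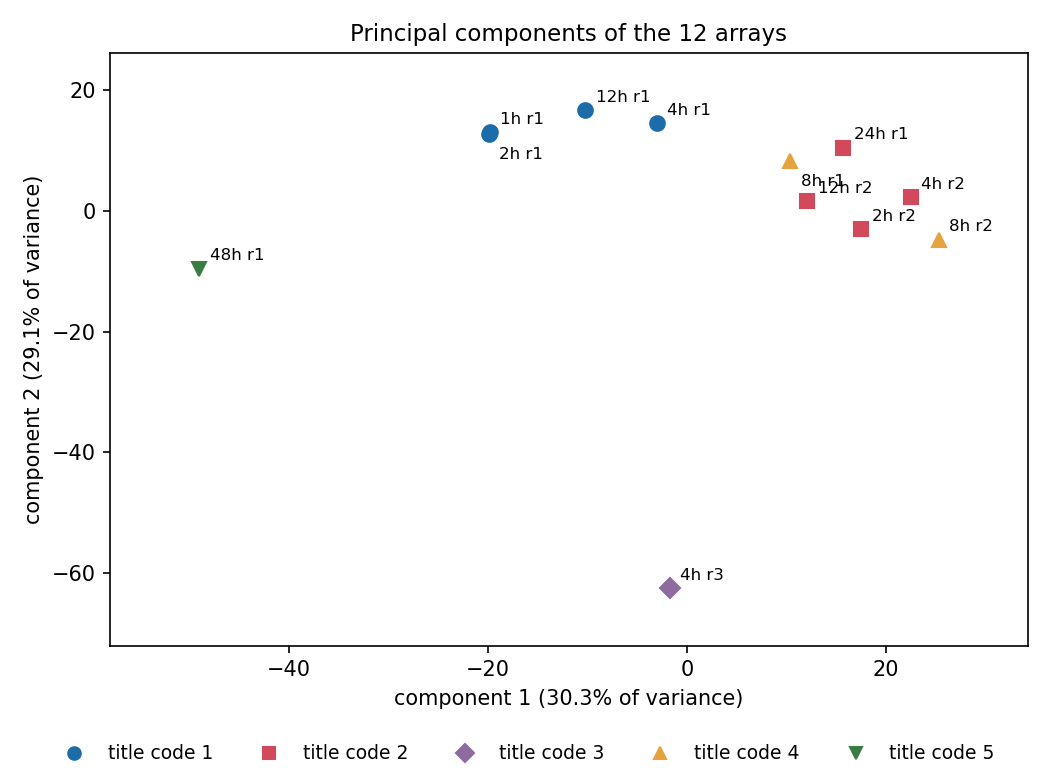
First and second principal components of the log2 signals of the 12 arrays with an assigned time, 1 point per array, with colour and shape for the title code. The 48h array lies at -49 on the first component and 4h replicate 3 at -62.6 on the second, apart from the rest.

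The slope along the hours asked which genes moved steadily over the time course, with all 12 arrays and log2 signal per doubling of the hours. TRIB1, a pseudokinase scaffold protein, fell by 0.67 ± 0.07 (SE, n = 12 arrays) on the log2 scale per doubling of the hours, 1.59-fold, with an adjusted p of 0.000698. FOSB, a subunit of the AP-1 transcription factor, fell by 0.85 ± 0.14 per doubling (adjusted p = 0.0448), from a log2 signal of 10.99 at 1h and 10.76 ± 0.49 (SD, n = 2) at 2h to 7.23 ± 0.19 (SD, n = 2) at 12h. The stress-responsive transcription factor ATF3 fell by 0.74 ± 0.12 (adjusted p = 0.0448), and HES1, a repressor downstream of Notch, fell by 0.60 ± 0.09 (adjusted p = 0.0325).

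These were 4 of the 7 probe sets called out of 11107 tested, and none rose. The others were KLF10, a transcription factor induced by TGF-beta, at -0.43 ± 0.06 (adjusted p = 0.0325), TSC22D1 at -0.40 ± 0.07 (adjusted p = 0.0448), and the kinase gene SGK1 at -0.29 ± 0.04 (adjusted p = 0.0325). At an unadjusted p under 0.05 there were 741 probe sets, against 555 that chance gives. With the title code as a replicate block 66 probe sets were called, 19 rising and 47 falling, among them 5 of the 7. Only the arrays of codes 1 and 2, from 1h to 24h, bear on that slope, since each other code holds a single time. The code as a random block gave 30 (2 rising, 28 falling). The fixed block gave 33 (8 rising, 25 falling) under median scaling and 33 (7 rising, 26 falling) with codes 2 and 4 merged. TSC22D1 and SGK1 had adjusted p-values of 0.0817 and 0.0766 in the block. With no dim-probe filter limma called 1 of 22215 probe sets, TRIB1, and in the block 0, with 2477 at an unadjusted p under 0.05. The count without the block was 1 without 2h replicate 1, 4h replicate 1, 4h replicate 2, 8h replicate 1, 8h replicate 2 or 12h replicate 1. It was 2 without 2h replicate 2, 3 without 12h replicate 2, 6 without 4h replicate 3, 8 without the 24h array and 13 without the 48h array. Without the 1h array it was again 7, 1 of them rising, but FOSB, ATF3, HES1, KLF10 and SGK1 lost their call (adjusted p from 0.0631 to 0.119). Without both 4h replicate 3 and the 48h array it was 82 (30 rising, 52 falling). TRIB1 stayed called with each of the 12 arrays left out in turn. FOSB stayed called only without the 48h array, with adjusted p from 0.0575 to 0.135 without any other. The blocked count was 0 without 12h replicate 1, 1 without 2h replicate 2, 6 without 2h replicate 1, 33 without 4h replicate 2, 99 without 12h replicate 2 and 169 without the 1h array.

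Of the following genes that the block added, CDK1 fell under the fixed rule through the F test, and the rest were named after their values were seen. CDK1, the kinase that drives entry into mitosis, fell by 0.45 ± 0.08 per doubling (adjusted p = 0.039 in the block, 0.779 without it), and the replication helicase gene MCM2 fell by 0.37 ± 0.05 (adjusted p = 0.0206 in the block). DUSP1, a phosphatase that switches off MAP kinases, fell by 0.51 ± 0.07 (adjusted p = 0.0206 in the block). COL18A1, a basement membrane collagen, rose by 0.40 ± 0.07 (adjusted p = 0.0307 in the block), and TGFBI, a secreted adhesion protein induced by TGF-beta, rose by 0.14 ± 0.02 (adjusted p = 0.017 in the block). Without the block the slopes of MCM2, DUSP1, COL18A1 and TGFBI were -0.12 ± 0.09, -0.33 ± 0.09, 0.10 ± 0.10 and 0.02 ± 0.05 (adjusted p = 0.871, 0.448, 0.912 and 0.971). Taken as genes rather than probe sets, the block called 48, of which 11 rose and 37 fell.

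**Figure D2:**
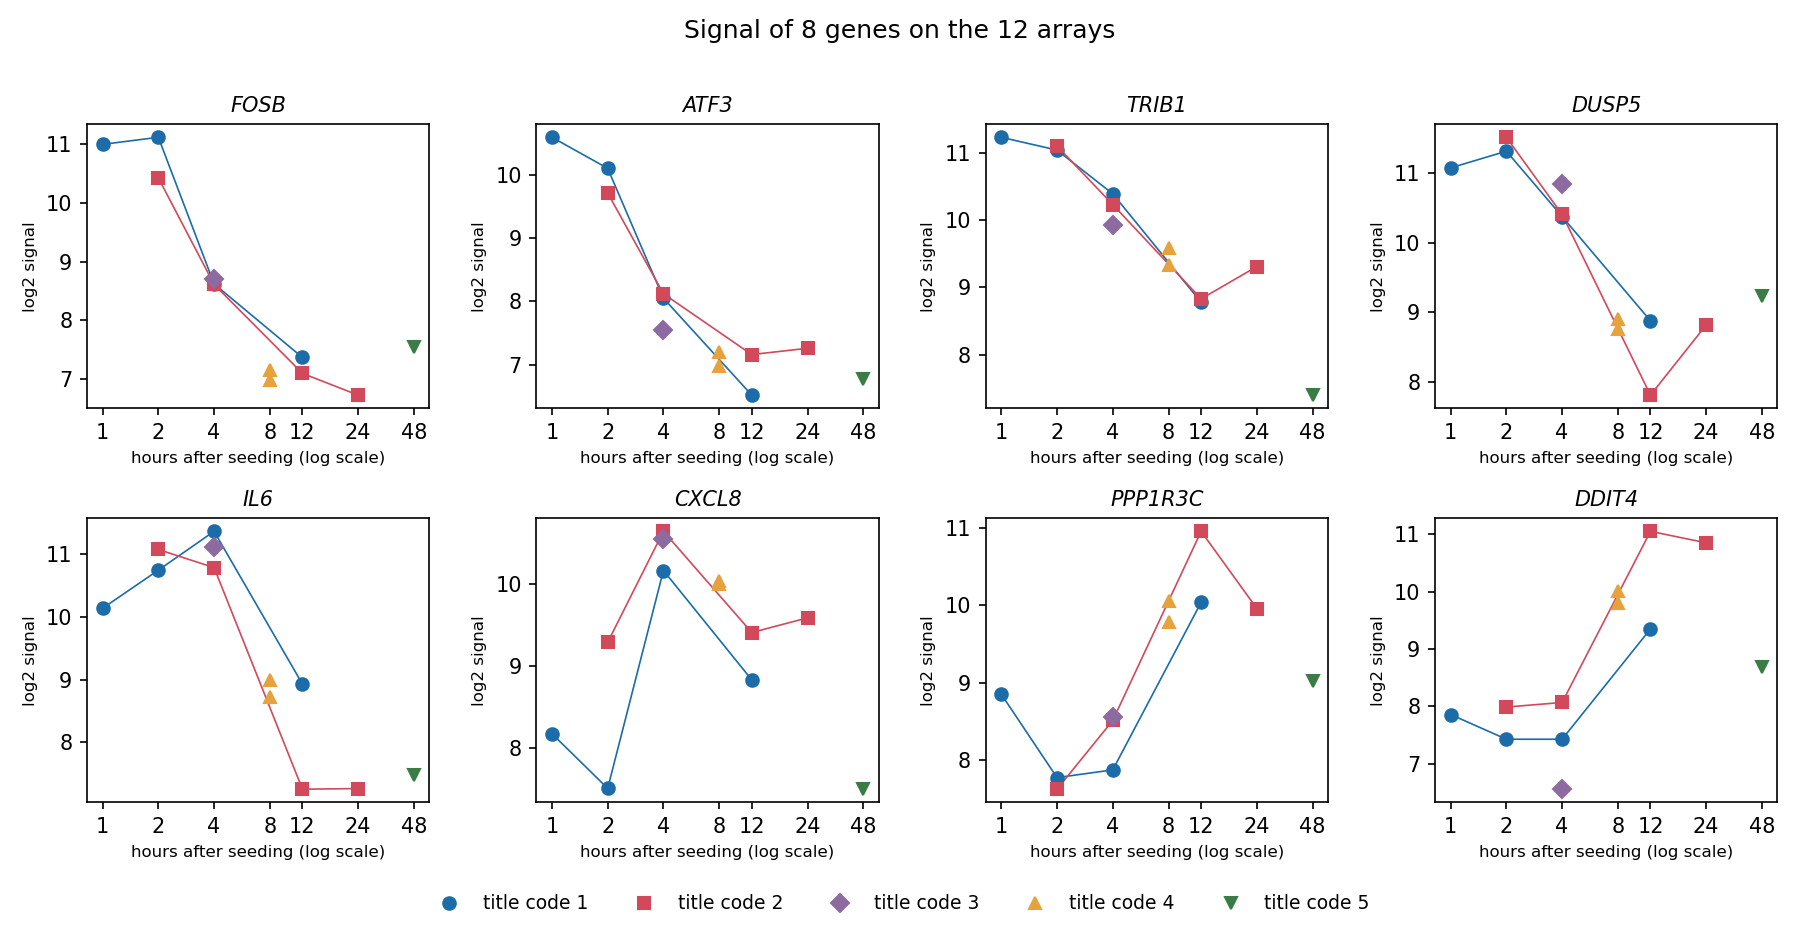
Log2 signal of 8 genes against hours after seeding (log axis), 1 point per array, with colour and shape for the title code and lines joining the arrays of codes 1 and 2. FOSB runs from 10.99 at 1h to 7.54 at 48h, while PPP1R3C has means of 7.70 at 2h and 10.50 at 12h.

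Among the gene lists, the immediate early genes, which growth factors switch on within minutes, fell along the time course. Of 28 members tested, 4 fell over all probe sets tested (FOSB, ATF3, KLF10 and SGK1) and 19 fell adjusted over the list alone, among them DUSP1 (adjusted p = 0.00547) and the survival gene MCL1 (adjusted p = 0.008). Their median slope was -0.299, and limma's camera test set the list below other genes with an adjusted p of 3.11e-26, or adjusted p = 0.0442 with an estimated correlation. In the block, 8 fell over all probe sets, and adjusted over the list alone 23 fell and 1 rose. FOS itself had a slope of -0.44 ± 0.13 (adjusted p = 0.47), EGR1 one of -0.28 ± 0.17 (adjusted p = 0.854) and MYC one of -0.18 ± 0.08 (adjusted p = 0.711).

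The cell cycle lists shifted lower too. All 33 tested genes of the G1/S and DNA replication list had negative slopes, with a median of -0.125 (camera adjusted p = 4.03e-14, and adjusted p = 0.173 with an estimated correlation). So did all 39 of the G2/M and mitosis list, with a median of -0.149 (camera adjusted p = 4.03e-14, and adjusted p = 0.384 with an estimated correlation). No member passed over all probe sets, and adjusted over the list alone 1 G1/S gene and 0 G2/M genes did by limma, with 10 and 8 at an unadjusted p under 0.05. At the top of the lists were CDC6, which loads the replicative helicase, at -0.28 ± 0.07 (adjusted p = 0.328), and HMMR, a spindle protein, at -0.20 ± 0.05 (adjusted p = 0.444). CCNB1, the mitotic cyclin, had -0.17 ± 0.08 (adjusted p = 0.788) and CCND1, the G1 cyclin, -0.19 ± 0.09 (adjusted p = 0.775). In the block, 23 G1/S and 35 G2/M genes fell adjusted over the list alone, and 2 of each list over all probe sets (MCM2 and RFC4, CDK1 and AURKB). The G2/M list was higher in code 2 than in code 1 by a median of 0.506 at matched times, and the immediate early list lower, by a median of -0.283. Camera with the preset correlation gave these code differences adjusted p-values of 8.88e-12 and 7.87e-05, and 0.705 for both with an estimated correlation. The preset test thus also calls lists between arrays of equal times.

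Inflammatory cytokines and NF-kB targets fell along the hours without the block and not with it. Of 18 tested, 0 passed over all probe sets and 3 fell adjusted over the list alone, with a median slope of -0.102 (camera adjusted p = 0.000669, and adjusted p = 0.23 with an estimated correlation). With the block the adjusted p was 0.0633, and without both 4h replicate 3 and the 48h array 0.0565. IL6, the main acute phase cytokine, had the smallest p of the list, with a slope of -0.81 ± 0.15 (adjusted p = 0.114), while CXCL8, a neutrophil chemokine, had -0.03 ± 0.18 (adjusted p = 0.984) and PTGS2, the inducible cyclooxygenase, -0.36 ± 0.19 (adjusted p = 0.825). The TGF-beta target list shifted lower, with 12 of 20 members lower, 8 higher and a median slope of -0.0367 (camera adjusted p = 0.000669, and adjusted p = 0.102 with an estimated correlation). By limma 1 member (TSC22D1) fell over all probe sets and 4 adjusted over the list alone. This call ended with the block (adjusted p = 0.234) and without the 48h array (adjusted p = 0.129). In neither does the 48h array bear on the slope, so they are not separate checks.

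Of the 25 lists with at least 5 members tested, 11 passed along the hours, 2 rising and 9 falling, and 1 with an estimated correlation. For the lists below, too, the block takes the 48h array out of the slope, as leaving it out does. Of the 6 lists named next, limma called 0 members of 5 and 1 angiogenic gene adjusted over the list alone. The ribosome biogenesis list shifted lower, with 25 of 29 members lower and 1 of these at an unadjusted p under 0.05 (camera adjusted p = 0.00203, and adjusted p = 0.459 with an estimated correlation), but not with the block (adjusted p = 0.053), without the 24h array (0.265) or without the 48h array (0.13). The list of angiogenic growth factors and receptors shifted lower, with 13 of 21 lower (adjusted p = 0.0221, and adjusted p = 0.121 with an estimated correlation), with HBEGF, an EGF-family growth factor, at -0.65 ± 0.14 (adjusted p = 0.188), but not with the block (0.0995) or without the 48h array (0.108). The actin cytoskeleton list shifted lower, with 23 of 31 lower and 4 of these at an unadjusted p under 0.05 (adjusted p = 0.0264, and adjusted p = 0.428 with an estimated correlation), but not without the 1h array (0.18) or the 24h array (0.265). The heat shock list shifted lower, with 19 of 23 lower and 2 of these at an unadjusted p under 0.05 (adjusted p = 0.0304, and adjusted p = 0.428 with an estimated correlation), but not without 2h replicate 2 (0.128), the 24h array (0.359) or the 48h array (0.11).

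The interferon-induced list shifted higher, with 15 of 18 higher and 2 of these at an unadjusted p under 0.05 (adjusted p = 0.0213, and adjusted p = 0.453 with an estimated correlation), with IRF9, a subunit of the interferon-activated transcription factor, at 0.22 ± 0.07 (adjusted p = 0.556), but not without the 24h array (0.586). The fibroblast identity list shifted higher, with 15 of 22 higher and 3 of these at an unadjusted p under 0.05 (adjusted p = 0.0389, and adjusted p = 0.428 with an estimated correlation), but not without 4h replicate 3 (0.161), 8h replicate 1 (0.0563), 12h replicate 1 (0.0697) or the 24h array (0.3), and not under median scaling (0.0622). Without the 24h array, 6 lists passed in all. Collagens and extracellular matrix had an adjusted p of 0.0666, and shifted higher in the block (6.26e-06, and adjusted p = 0.222 with an estimated correlation), with 8 of 35 members rising adjusted over the list alone. They also passed without the 1h array (0.037), 2h replicate 1 (0.0474) or the 48h array (9.71e-05). Smooth muscle markers had an adjusted p of 0.0642 and shifted lower in the block (0.0209, and adjusted p = 0.504 with an estimated correlation), with 2 of 9 members falling adjusted over the list alone. COL1A1, the main fibrillar collagen, had a slope of 0.04 ± 0.03 (adjusted p = 0.878), FN1, fibronectin, 0.00 ± 0.03 (adjusted p = 0.991), and the contractile actin gene ACTA2 -0.10 ± 0.04 (adjusted p = 0.692).

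Camera gave adjusted p-values of 0.074 for matrix proteases and inhibitors and for cholesterol synthesis, 0.0642 for the proteasome, 0.196 for integrins and focal adhesion, 0.242 for oxidative stress and metallothioneins, 0.297 for cytoplasmic ribosomal proteins, 0.561 for p53 targets and for the mitochondrial respiratory chain, 0.674 for hypoxia and glycolysis, 0.71 for quiescence and FOXO genes and 0.907 for the unfolded protein response. Of other cell types, 5 epithelial markers gave 0.907. Endothelial and leukocyte markers had 1 and 3 members tested, too few for the test, with median slopes of 0.0387 and 0.0305. For the hypoxia, unfolded protein, p53 and epithelial lists the median slope lay above 0 and the direction of the camera test below it. The remaining fixed genes had slopes of -0.28 ± 0.16 for VEGFA, the endothelial growth factor, -0.11 ± 0.07 for MMP1, interstitial collagenase, 0.01 ± 0.06 for HMOX1, heme oxygenase, and 0.33 ± 0.10 for TXNIP, the thioredoxin inhibitor (adjusted p = 0.84, 0.856, 0.978 and 0.536).

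**Figure D3:**
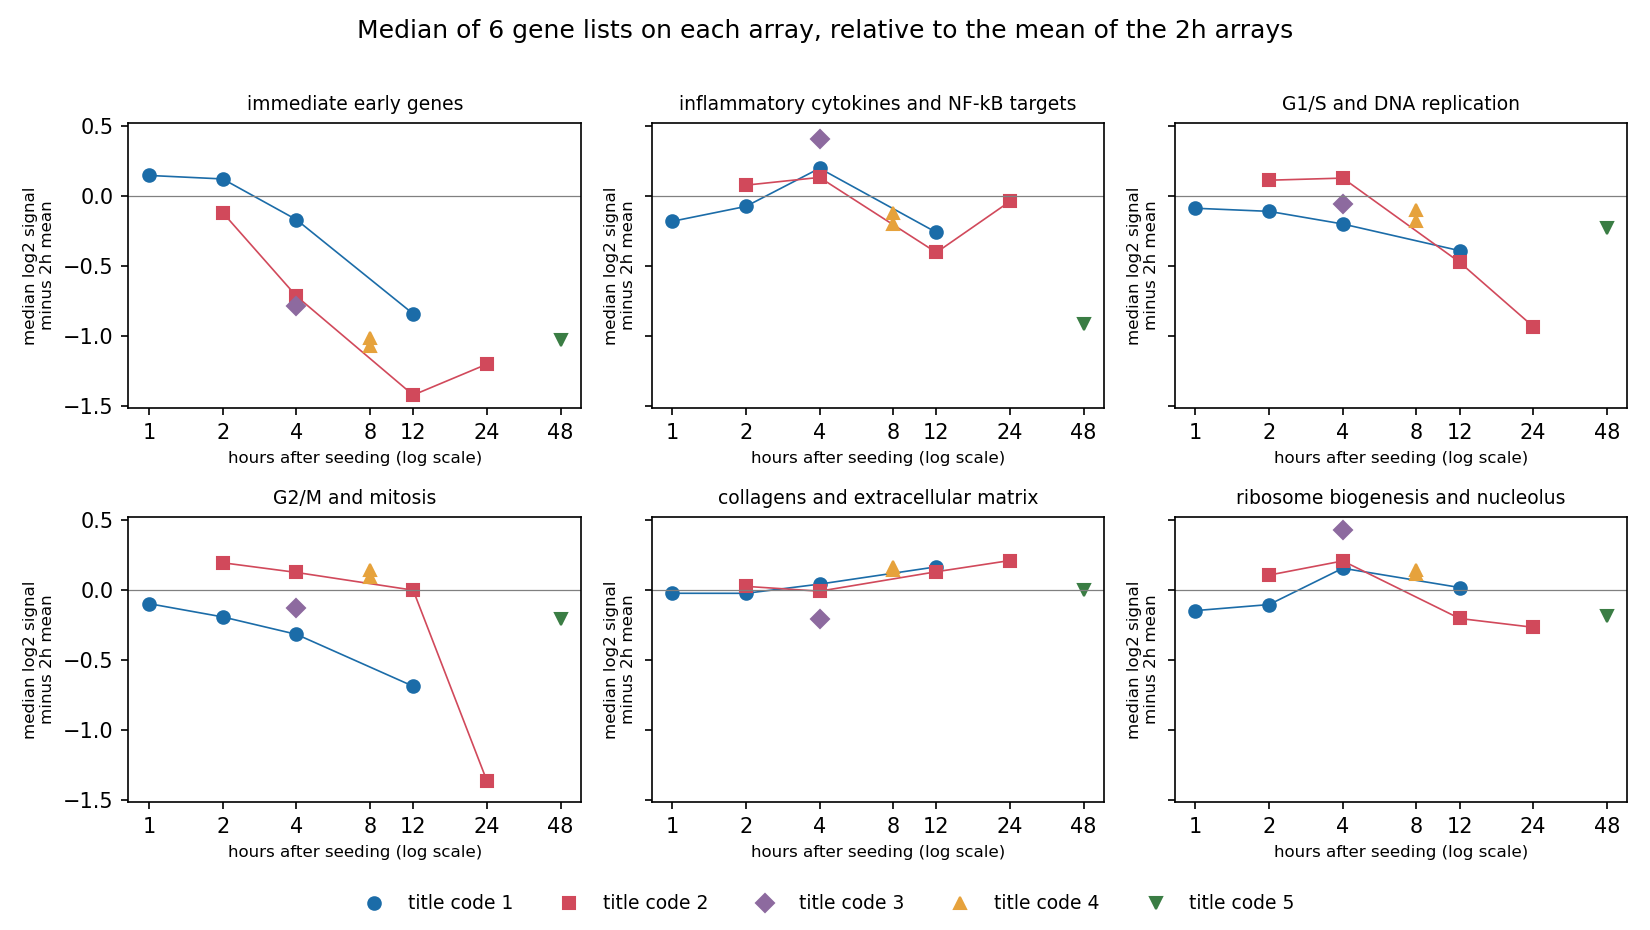
Median over the members of 6 gene lists of the log2 signal minus the mean of the 2h arrays, against hours after seeding (log axis), 1 point per array, with colour and shape for the title code and lines joining the arrays of codes 1 and 2. The immediate early list is at 0.145 at 1h, 0.12 on 2h replicate 1, which shares its code, and -1.20 at 24h, and the G2/M list at -1.36 at 24h.

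The comparison of 12h with 2h asked what differed at the last time with replicates. Under the main settings it gave the largest number of calls among the times with replicates. With 1 probe set per gene, 8h and 12h against 2h gave 11 each. FOSB was 11.5-fold lower at 12h, a log2 change of -3.53 ± 0.25 (SE, n = 2 arrays at each time; adjusted p = 0.00276). DUSP5, a nuclear phosphatase that inactivates ERK, was 8.42-fold lower (-3.07 ± 0.34, adjusted p = 0.0211), ATF3 8.35-fold lower (-3.06 ± 0.29, adjusted p = 0.0102) and TRIB1 4.83-fold lower (-2.27 ± 0.21, adjusted p = 0.0102). PPP1R3C, which targets protein phosphatase 1 to glycogen, was 6.99-fold higher (2.80 ± 0.34, adjusted p = 0.0322), from a log2 signal of 7.70 ± 0.11 (SD, n = 2) at 2h to 10.50 ± 0.65 (SD, n = 2) at 12h.

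The clock gene PER2 was 4.42-fold lower at 12h (adjusted p = 0.0322), the immediate early gene IER2 3.42-fold lower (adjusted p = 0.0427), ID3, an inhibitor of basic helix-loop-helix factors, 3.28-fold lower (adjusted p = 0.0211), and RHOB, a small GTPase, 3.27-fold lower (adjusted p = 0.0372). With 1 more probe set each for NR4A1, a nuclear receptor (-2.01 ± 0.26), and UGCG, glucosylceramide synthase (-1.87 ± 0.24), both named after their values were seen, 11 probe sets were called, 1 higher and 10 lower. At an unadjusted p under 0.05 there were 543, where chance gives 555. The count was 1 without 2h replicate 1 or 2h replicate 2, 6 without 4h replicate 1, 3 without 4h replicate 2, 8h replicate 1 or 8h replicate 2, 34 without 4h replicate 3, 20 without 12h replicate 1 and 0 without 12h replicate 2, where FOSB had an adjusted p of 0.0534. Without both 4h replicate 3 and the 48h array it was 37. With no dim-probe filter it was 1, the higher probe set of PRPS1L1, named after its values were seen. The representing probe set of NR4A1 had -0.06 ± 0.27 (adjusted p = 0.9997) and that of UGCG -1.29 ± 0.25 (adjusted p = 0.184).

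With the title code as a block, over the 6 arrays of codes 1 and 2 at 2h, 4h and 12h, 146 probe sets were called between 12h and 2h, 37 higher and 109 lower, including all 11. With no dim-probe filter limma called 0 of 22215 in the block, with 2036 at an unadjusted p under 0.05. Counted as genes by their representing probe set, the filtered fit in the block called 105, with 22 higher and 83 lower. IL6 was 7.12-fold lower at 12h (-2.83 ± 0.37, adjusted p = 0.0121 in the block, 0.126 without it). Of the following genes, HBEGF, DDIT4 and MFAP2 fell under the fixed rule through other results, and the rest were named after their values were seen. HBEGF was 6.05-fold lower (adjusted p = 0.00589 in the block), the ERK phosphatase gene DUSP6 3.57-fold lower (adjusted p = 0.0099) and JUNB, an AP-1 subunit, 3.17-fold lower (adjusted p = 0.0116). DDIT4, a stress-induced inhibitor of mTORC1, was 5.62-fold higher (2.49 ± 0.27, adjusted p = 0.007 in the block, 0.416 without it). CDKN1B, the inhibitor p27 of cyclin-dependent kinases, was 2.41-fold higher (adjusted p = 0.0116), TGFB1, the growth factor, 2.45-fold higher (adjusted p = 0.00854), and MFAP2, a microfibril protein, 2.52-fold higher (adjusted p = 0.021). Without the block limma gave adjusted p-values of 0.126 for HBEGF, 0.5 for DUSP6, 0.184 for JUNB, 0.931 for CDKN1B, 0.556 for TGFB1 and 0.782 for MFAP2.

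Of the fixed genes, FOS was 2.71-fold lower in the block (adjusted p = 0.0094, and 0.126 without it) and MYC 2.25-fold lower (adjusted p = 0.03, and 0.556 without it). The log2 differences of the rest at 12h, none called in either fit, were -0.84 ± 0.74 for EGR1, 0.72 ± 0.50 for CXCL8, -1.16 ± 0.41 for PTGS2, -0.79 ± 0.76 for VEGFA, 0.26 ± 0.20 for HMOX1, 0.21 ± 0.15 for COL1A1, 0.15 ± 0.13 for FN1, -0.17 ± 0.21 for ACTA2, -0.02 ± 0.39 for MMP1, -0.35 ± 0.36 for CCNB1, -0.85 ± 0.57 for CCND1 and 1.60 ± 0.39 for TXNIP.

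Immediate early genes were lower at 12h as a list, with a median of -1.11 over 28 members (camera adjusted p = 2.5e-31, and adjusted p = 0.0732 with an estimated correlation). Over all probe sets 4 members fell, and 17 adjusted over the list alone. In the block, 15 fell over all probe sets, and adjusted over the list alone 23 fell and 1 rose. All 33 G1/S genes were lower, with a median of -0.478 (adjusted p = 2.3e-11, and adjusted p = 0.169 with an estimated correlation), and 37 of 39 G2/M genes were lower, with a median of -0.348 (adjusted p = 3.01e-08, and adjusted p = 0.375 with an estimated correlation). No member of either list passed on its own by limma, with 7 and 4 at an unadjusted p under 0.05, and in the block 14 and 10 fell adjusted over the list alone, with MCM2, RRM2, a subunit of ribonucleotide reductase, CDK1, AURKA, a spindle kinase, and TRIP13 falling over all probe sets. Without 12h replicate 1 the G2/M median was -0.00287 and its adjusted p 0.204.

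The inflammatory list fell between 2h and 12h, with a median of -0.371 over 18 members and 4 falling adjusted over the list alone (adjusted p = 1.48e-05, and adjusted p = 0.165 with an estimated correlation). In the block, 9 fell and 1 rose adjusted over the list alone, with IL6 and LIF, an IL-6 family cytokine (2.85-fold lower, adjusted p = 0.00854), over all probe sets. The collagen and extracellular matrix list shifted higher, with a median of 0.172 and 27 of 35 members higher (adjusted p = 0.00343, and adjusted p = 0.25 with an estimated correlation), with 0 members called by limma adjusted over the list alone and 3 at an unadjusted p under 0.05. The fibroblast identity list had an adjusted p of 0.0505 and shifted higher with the block (adjusted p = 0.0325, and adjusted p = 0.443 with an estimated correlation), with FOXF1, a lung mesenchyme factor, and PDGFRA, a growth factor receptor, 1.59- and 1.77-fold higher and SNAI2 1.75-fold lower. They also passed without 2h replicate 1 (0.033), 4h replicate 1 (0.0419), 8h replicate 1 (0.0422) or 8h replicate 2 (0.0435), and under median scaling (0.0235).

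The actin cytoskeleton list shifted lower at 12h, with 18 of 31 members lower, 0 called by limma adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.0196, and adjusted p = 0.25 with an estimated correlation), but not without 2h replicate 2 (0.0617), 4h replicate 3 (0.0501) or 12h replicate 2 (0.137), or under median scaling (0.0555). The angiogenic list shifted lower, with 13 of 21 lower (adjusted p = 0.0204, and adjusted p = 0.209 with an estimated correlation), with HBEGF and ANGPT1, angiopoietin 1 (1.85-fold lower), among 3 falling and PDGFRA rising in the block. This list did not pass without 2h replicate 2 (0.105), 4h replicate 3 (0.0551) or 12h replicate 2 (0.16). In all, 7 of 25 lists passed with the preset correlation and 0 with an estimated one, and 8 in the block.

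The comparison of 4h with 2h asked what moved first. No probe set was called by limma (0 of 11107, with 247 at an unadjusted p under 0.05, where chance gives 555). The title code block called 2, both lower at 4h: FOSB at -2.15 ± 0.19 (adjusted p = 0.0152) and ID1, an inhibitor of basic helix-loop-helix factors, at -1.53 ± 0.13 (adjusted p = 0.0152). The code as a random block called 16, of which 6 were higher and 10 lower. Among genes with the smallest p without the block, FOSB was 4.34-fold lower (-2.12 ± 0.23, n = 2 and 3 arrays, adjusted p = 0.092), ID1 3.26-fold lower (adjusted p = 0.144) and the neurotrophin gene BDNF had -1.27 ± 0.19 (adjusted p = 0.144). On the higher side, not called either, CXCL8 had 2.06 ± 0.45 (adjusted p = 0.811), PTGS2 1.70 ± 0.37 (adjusted p = 0.811), STC1, stanniocalcin 1, 0.92 ± 0.21 (adjusted p = 0.91) and TENT5A 1.12 ± 0.21 (adjusted p = 0.436).

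At 4h against 2h, 6 of 25 lists passed with the preset correlation and 0 with an estimated one. Immediate early genes fell by a median of 0.531, 6 of 28 of them adjusted over the list alone (camera adjusted p = 1.88e-16, and adjusted p = 0.286 with an estimated correlation). The ribosome biogenesis list shifted higher, with 27 of 29 higher, 0 called by limma adjusted over the list alone, 3 at an unadjusted p under 0.05 and a median of 0.249 (adjusted p = 1.31e-06, and adjusted p = 0.337 with an estimated correlation). The inflammatory list shifted higher at this time, with 3 of 18 members rising and 1 falling adjusted over the list alone and a median of 0.162 (adjusted p = 0.0142, and adjusted p = 0.337 with an estimated correlation). These 3 lists also passed in the block (1.23e-10, 0.000194 and 0.0417), with adjusted p = 0.402, 0.985 and 0.985 with an estimated correlation. The inflammatory median there was 0.0459, with 9 members higher and 9 lower. The proteasome (0.0142, 21 of 27 higher) and respiratory chain (0.0208, 30 of 39 higher) lists shifted higher and collagens (0.0494, 26 of 35 lower) lower, with adjusted p = 0.449, 0.722 and 0.449 with an estimated correlation, and none of these passed in the block (0.0804, 0.328 and 0.973). Limma called 0 members of these 3 lists adjusted over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05.

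At 8h against 2h, 3 probe sets were called, all lower. FOSB was 12.9-fold lower (-3.69 ± 0.25, n = 2 arrays at each time, adjusted p = 0.00187), ATF3 7.05-fold lower (-2.82 ± 0.29, adjusted p = 0.0305), and a second probe set of NR4A1, named after its values were seen, had -2.33 ± 0.26 (adjusted p = 0.0383). At an unadjusted p under 0.05 there were 368. DUSP5, IER2, LIF, TRIB1 and SIK1 each had an adjusted p of 0.0535, and PPP1R3C, with a log2 difference of 2.23 ± 0.34, one of 0.112. Both 8h arrays had a title code that no other time shared, so a shift of that code and the time cannot be told apart here. With the code as a random block 1 probe set was called, lower at 8h. The count was 1 without 2h replicate 1, 4h replicate 1, 4h replicate 2 or 8h replicate 1, 0 without 8h replicate 2, 15 without 4h replicate 3 and 6 without 12h replicate 1 or 12h replicate 2. With no dim-probe filter limma called 0, with 808 at an unadjusted p under 0.05.

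By 8h the immediate early list had fallen by a median of 1.06, 15 of 28 members adjusted over the list alone (camera adjusted p = 3.18e-35, and adjusted p = 0.0563 with an estimated correlation). The inflammatory list fell (0.0155, and adjusted p = 0.473 with an estimated correlation), with 3 members falling and 2 rising adjusted over the list alone, and the G1/S list shifted lower (0.0281, and adjusted p = 0.559 with an estimated correlation), with 24 of 33 members lower, 0 called by limma adjusted over the list alone and 0 at an unadjusted p under 0.05. The respiratory chain (0.00841), cytoplasmic ribosomal proteins (0.0143), proteasome (0.0143), collagens (0.0155) and ribosome biogenesis (0.0442) lists shifted higher, with medians of 0.16, 0.101, 0.125, 0.122 and 0.123 and with adjusted p = 0.559, 0.473, 0.473, 0.473 and 0.559 with an estimated correlation. Limma called 0 members of these 5 lists adjusted over the list alone, with 1 collagen and 1 ribosome biogenesis gene at an unadjusted p under 0.05. The G2/M list had a median of 0.161 at 8h (adjusted p = 0.235).

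The test for any difference among 2h, 4h, 8h and 12h, which also finds genes that rise and fall again, called 1 probe set, FOSB (adjusted p = 0.00605), with 465 at an unadjusted p under 0.05. Its count was 0 without 8h replicate 1, 8h replicate 2 or 12h replicate 2 and 5 without 4h replicate 3 or 12h replicate 1. With the block, over 2h, 4h and 12h, it was 141. Not called along the slope and next by p were DUSP5, LIF, PPP1R3C, ID3, PER2, RHOB, IER2, SIK1, HBEGF and IL6. IL6 had log2 signals of 10.92 ± 0.23 (SD, n = 2) at 2h, 11.09 ± 0.29 (SD, n = 3) at 4h, 8.87 ± 0.19 (SD, n = 2) at 8h and 8.09 ± 1.19 (SD, n = 2) at 12h.

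The times of 1h, 24h and 48h had 1 array each, so their differences from the mean of the 2h arrays are values without a test. At 1h, FOS was 4.14-fold, EGR1 4.10-fold and HES1 3.54-fold above 2h. Against 2h replicate 1 alone, which shares the title code of the 1h array, a reference chosen after the values were seen, they were 4.68-, 1.87- and 2.52-fold higher. The immediate early list had a median of 0.145 at 1h, at percentile 100 of 10000 random lists matched on signal, but -0.0828 against 2h replicate 1, at percentile 3.67, with 12 members higher and 16 lower. The inflammatory list had -0.182, at percentile 0.46, but -0.00889 against 2h replicate 1, at percentile 45.4. The 5 epithelial markers had -0.498, with 2 higher and 3 lower, at percentile 0.02, and -0.43 against 2h replicate 1, with 0 higher, at percentile 0.04. Random lists ignore the correlation among members of a list, so none of these percentiles is a test. At 24h the immediate early median was -1.20 and all 39 G2/M and all 33 G1/S genes lay below 2h, with medians of -1.36 and -0.932, each at percentile 0. Against 2h replicate 2, which shares the code of the 24h array, these medians were -1.03, -1.61 and -1.15, each at percentile 0. Smooth muscle and epithelial markers were also lower there, with medians of -0.452 (0 of 9 higher) and -0.402 (0 of 5 higher), at percentiles 0.23 and 2. The interferon-induced, quiescence and collagen lists had medians of 0.436, 0.357 and 0.209 at 24h, at percentiles 100, 99.8 and 99.8, and 0.419, 0.552 and 0.284 against 2h replicate 2. At 48h the immediate early and inflammatory medians were -1.03 and -0.916 and that of TGF-beta targets -0.418, each at percentile 0, while cholesterol synthesis had 0.367, at percentile 100. The G2/M median was -0.209 at 48h.

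Counting genes whose 24h and 48h arrays both lay outside the range of the 6 arrays up to 4h, 337 of 6938 lay above and 378 below, where exchangeable arrays would give 248 on each side. In a check added after the counts were seen, of the 28 pairs of these 8 arrays, the real one included, 8 gave as many above and 6 as many below, so the counts did not set the late arrays apart. The highest pair, 4h replicate 3 with the 48h array, gave 1199 and 778. The 6 highest by the fixed rule were DDIT4 (8.84-fold at 24h and 1.97-fold at 48h over 2h), ADM, the vasodilator peptide adrenomedullin (2.99 and 5.63), PPP1R3C (4.81 and 2.51), TXNIP (5.04 and 2.01), SPATA20 (1.83 and 2.28) and DHCR7, the last enzyme of cholesterol synthesis (2.26 and 1.76). The 6 lowest were FOSB (16.4-fold below 2h at 24h and 9.29-fold at 48h), IL6 (12.6 and 10.8), ID3 (15.3 and 5.58), ATF3 (6.25 and 8.73), HBEGF (8.52 and 5.93) and the cytokine gene IL11 (8.65 and 5.51). The 24h array shared its code with 3 others, and the 48h array shared its code with none.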

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

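The tests of probe sets of one gene and of the 48h array were chosen only after the result was seen, and the tests of random assignments and of RNA degradation were written before.

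The array whose labels give 2 different times stood outside the range of the 12 assigned arrays in its control probes. Its ratio of GAPDH 3' to 5' signal was 7.17, against 0.962 to 1.66, its ratio for actin was 3.81, against 0.675 to 1.07, and its BioB spike signal was 510, against at most 345. An 18S ribosomal RNA control probe read 844 on 4h replicate 1 and 277 on the 48h array, over 3 times the median of 57.65 on the 12 arrays, a limit that was changed after the values were seen.

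Times were assigned to the 12 arrays at random. Of 100 assignments, the real one included, 2 called at least as many probe sets along the slope as the 7 of the real times. That share lay under 0.05, but arrays of one title code deviated together. They are therefore not exchangeable, and the share cannot exclude chance. The highest other assignment called 197, several times the real count, which points to a structure of the samples: its hours correlated at 0.808 with the first principal component. The real hours correlated at -0.141 with the first component and -0.0282 with the second. With the title code as a block and times assigned within codes 1 and 2, 2 of 100 gave at least the real 66, and the highest other gave 127.

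Arrays of one title code deviated together, and 1038 of 11107 probe sets differed between codes 1 and 2 at matched times, 472 higher and 566 lower in code 2, such as CCN1, a secreted matrix protein, at -2.32 ± 0.16. RNA degradation may contribute: the code difference correlated over probe sets at 0.514 with the difference between the 8h arrays, which share a code and have GAPDH ratios of 1.03 and 1.41, a correlation across probe sets that are not independent. The 8h arrays also differ in the letter of their titles, A and B, so their difference need not be degradation alone. The GAPDH ratios of the codes overlapped, 0.962 to 1.17 in code 1 and 0.99 to 1.18 in code 2, higher in code 2 at 2 of 3 matched times, while the actin ratio (0.697 to 0.828 and 0.719 to 0.844) was higher in code 2 at 3 of 3 and the signal of the Cre hybridisation control (4227 to 9180 and 2412 to 3614) at 0 of 3. Hybridisation that differs by probe could not be decided, since the code difference correlated at 0.49 between the 2 brightest probe sets of a gene, where the difference between 12h and 2h gave 0.697. Of 39 G2/M genes, 37 were higher in code 2 at matched times. The design names no biological difference between the codes, so no biological explanation was tested and none is excluded.

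The array 4h replicate 3 stood apart from the other 4h arrays, with a GAPDH ratio of 1.66. Its deviation correlated at only 0.197 between the 2 brightest probe sets of a gene, so probe sets of the same gene disagreed. Hybridisation that differs by probe could produce this, but RNA degradation can make such probe sets disagree too. The correlation therefore cannot tell these causes apart, and both stay open. The deviation of this array correlated at 0.205 with the difference between the 8h arrays. That value is too low to bear degradation out and too high to exclude it. No biological explanation was tested, since this array shares its time with 2 other arrays and its title code with none.

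Immediate early genes were higher at 48h than at 24h in 17 of 28 cases, with a median of 0.497, and G2/M genes in 37 of 39, with a median of 1.18. For both lists a shift of the title code and a change with time cannot be told apart, since the 48h array shares its code with no other array. Code 2, which holds the 24h array, had the higher G2/M signal at matched times, with a median of code 1 minus code 2 of -0.506. Its SE of 0.0743 is over the 39 genes, which are not independent, and does not measure the spread between arrays. Camera with an estimated correlation gave this difference an adjusted p of 0.705. Over the 28 immediate early genes the step from 24h to 48h correlated at 0.539 with code 1 minus code 2, and over all probe sets at 0.442. A change with time was not tested, with 1 array at each time.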

How the results depend on the processing

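Chosen only after the result was seen were the settings that left out 4h replicate 3 with the 48h array, the GAPDH ratio as a covariate, other scalings, filters and arrays within the fixed blocked fits, the 2h array of the same code as the reference for 1h and 24h and the list tests without each array; the others were planned. Probe set counts of the slope were within 1.5 times of 7 with values as deposited (6), no floor (7), a floor at the 40th percentile (7), 1 probe set per gene (9), ranks of the hours (9), the GAPDH covariate (7) and within code 1 (8, all falling, of which 2 were among the 7) or code 2 (7, of which 4 rose, 3 fell and 0 were among the 7). Those of 12h against 2h were within 1.5 times of 11 as deposited (9), with no floor (11) and in a fit on all 12 arrays (11). In the slope fit with the GAPDH covariate, 716 probe sets were called for the ratio itself, against 7 for the hours. For the ratio, 2849 had an unadjusted p under 0.05. The ratio was 1.66 on 4h replicate 3 and 1.41 on 8h replicate 2, and at most 1.18 on the rest. Its count therefore leans on these arrays and cannot be read as RNA quality across the series. Among named genes and lists, along the slope and at 12h against 2h, no called value changed direction. Directions of other calls, and under the settings within the blocked fits, were not compared. An uncalled value has no direction. Of untested list medians at 1h outside the range of random lists, those of immediate early genes (-0.0828), cholesterol synthesis (-0.0866) and heat shock proteins (0.0276) turned their sign against the 2h array of the same code. For each change below the cause was not tested.

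Median scaling gave 3 probe sets along the slope and 7 for 12h against 2h. Values as deposited gave 2 in the F test. A floor at the 40th percentile gave 4 in the F test and 9 for 8h against 2h. With no dim-probe filter the slope had 1, 8h against 2h had 0 and 12h against 2h had 1, and with a filter at the 75th percentile the slope had 4, the F test 0, 8h against 2h 0 and 12h against 2h 5. Without the intensity trend eBayes gave 4 along the slope and 3 in the F test. With 1 probe set per gene the F test had 13, 4h against 2h had 1 and 8h against 2h had 11. The slope over 2h to 12h only had 13. Without both 4h replicate 3 and the 48h array the slope had 82, the F test 5, 8h against 2h 15 and 12h against 2h 37.

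The title code as a replicate block gave 66 along the slope, 2 for 4h against 2h, 146 for 12h against 2h and 141 in the F test over 2h, 4h and 12h. With codes 2 and 4 merged in the block the slope had 33. As a random block the code gave 30 along the slope (2 rising, 28 falling), 74 in the F test, 16 for 4h (6 higher, 10 lower), 1 lower for 8h and 131 for 12h against 2h (36 higher, 95 lower). Within the blocked fits, median scaling gave 33 along the slope and 95 for 12h against 2h, values as deposited gave 43 and 96, and no dim-probe filter gave 0 and 0. On all arrays of codes 1 and 2 the blocked 12h contrast gave 143. No contrast of 8h was run with the code as a fixed block, because both 8h arrays have a code of their own. Only the slope with codes 2 and 4 merged paired them with other times in a fixed block. The block changed no list call other than those given beside their results.

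Leaving out 1 array at a time gave 1 to 13 along the slope, 0 to 5 in the F test, 0 to 0 for 4h, 0 to 15 for 8h and 0 to 34 for 12h against 2h, and 0 to 169 for the blocked slope. Where this left 1 array at a time, that array was assumed to vary like the other groups. The number of lists past the threshold ran from 6 to 15 along the slope and from 5 to 10 at 12h, and with an estimated correlation it was 1 and 0. Lists that came to pass with an array left out, along the slope, were cholesterol synthesis (without the 1h array 0.0159, 2h replicate 1 0.019, 8h replicate 2 0.0445 or 12h replicate 2 0.0176), the proteasome (without the 1h array 0.0159, 2h replicate 1 0.0231, 2h replicate 2 0.0393, 8h replicate 2 0.0399 or 12h replicate 2 0.0395), smooth muscle (without the 1h array 0.0299, 2h replicate 1 0.0358 or 12h replicate 2 0.0386), matrix proteases (without 2h replicate 2 0.0393 or 12h replicate 2 0.0461), and, without the 48h array, ribosomal proteins (0.0479) and the respiratory chain (0.0119). At 12h they were TGF-beta targets (0.0499) and heat shock proteins (0.0102) without 2h replicate 1, cholesterol synthesis (0.0352) and the respiratory chain (0.0103) without 2h replicate 2, and these (0.0494 and 0.0445) and ribosomal proteins (0.0494) without 12h replicate 1. Median scaling let the proteasome pass along the slope (0.00431), as did the mean over all probes of a gene (0.0364), and ribosomal proteins at 12h (0.0235). Lists at 4h and 8h were not run without single arrays.

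Of the list values without 1 array, 469 kept their side of the threshold, 30 came to pass it and 21 no longer did, and of those in other settings 328, 10 and 30, with 3 reversed. For named genes these were 3836, 25 and 105 without 1 array and 5177, 171 and 54 in other settings. Probe sets near the floor of 46.74 have signals that limit what a fold can show, and the median over all probe sets of 8h minus 2h was 0.00181 with quantile normalisation, 0.0861 with median scaling and 0.0765 as deposited.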

Other observations

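The genes named next were put together only after the values were seen, and their values compare 12h with 2h in the fit with the title code as a block. Some of them, such as HES1 and PER2, also fell under the fixed rule through other results. SPRY4, an inhibitor of receptor tyrosine kinase signalling, was 3.26-fold lower at 12h (-1.71 ± 0.28, adjusted p = 0.0291). HES1 was 3.16-fold lower, JAG1, a ligand of Notch, 2.42-fold lower and the transcriptional repressor gene HEY1 2.35-fold lower (adjusted p = 0.0156, 0.012 and 0.0285). Of the genes looked at with them, the Notch receptor genes NOTCH2 and NOTCH3 had -0.05 ± 0.15 and 0.62 ± 0.17 (adjusted p = 0.919 and 0.135), so 3 of 5 were called. SPRY4 was 1 of 5 called among 10, with DUSP5, DUSP6, HBEGF and LIF, while SPRY2 had -1.76 ± 0.37, SPRED2 -0.63 ± 0.20, ETV5 -0.22 ± 0.19, ETV4 -0.10 ± 0.17 and PHLDA1 0.43 ± 0.19 (adjusted p = 0.0674, 0.201, 0.652, 0.853 and 0.329). Without the block limma gave adjusted p-values of 0.296 for SPRY4, 0.184 for HES1, 0.778 for JAG1 and 0.556 for HEY1.

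In the same fit the clock gene PER2 was 4.42-fold lower, BHLHE40, a repressor of the clock, 4.7-fold lower and the nuclear receptor gene NR1D2 3.08-fold lower (adjusted p = 0.00373, 0.00374 and 0.0152). BMAL1, the activator of the clock, had 0.91 ± 0.19 (adjusted p = 0.0674). Of 10 clock genes looked at, PER2, BHLHE40 and NR1D2 were the 3 called, and among the others NPAS2 had 0.52 ± 0.21, CRY2 -0.25 ± 0.15 and CLOCK 0.06 ± 0.16 (adjusted p = 0.3, 0.462 and 0.914). Without the block PER2, BHLHE40 and NR1D2 had adjusted p-values of 0.0322, 0.237 and 0.556. On the single 24h array PER2 read 7.58, NR1D2 9.33 and BHLHE40 9.98, each above both of its 12h arrays. On the single 48h array BHLHE40 read 7.69, below both of its 12h arrays, NR1D2 7.79, between them, and PER2 6.70, above both.

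On the array with 2 different times in its labels, 2706 of 11107 tested probe sets (24.4%) lay below the range of the 12 assigned arrays and 2484 (22.4%) above it. CXCL8 read 11.11, against at most 10.65 on the 12 arrays, VEGFA 11.03, against at most 10.82, and MMP1 11.48, against at most 11.39. The other 12 fixed genes lay within the range of the 12 arrays, with FOS at 6.47 and IL6 at 8.56. Its mean Spearman correlation with the 12 arrays was 0.936 and its median signal 135.9.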
